A study of Mus musculus with 4 samples.

How the data were processed

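RNA was measured in immunoprecipitates from mouse neurospheres, floating cultures of neural stem and precursor cells. Per the labels, the cultures came from the ventricular-subventricular zone (V-SVZ), the stem cell niche beside the lateral ventricles, of wild-type CD1 mice at postnatal day 7 or 8, and were kept for 7 days. RNA immunoprecipitation pulls down a protein with an antibody and sequences the RNA that comes with it. An antibody against 4E-T, an eIF4E-binding protein of processing bodies (P-bodies) encoded by Eif4enif1, was used in 2 libraries, and a control IgG in the other 2. The labels number each pair Exp1 and Exp2. Per the labels' protocols, RNA was isolated with the Magna RIP kit, cDNA was made with SMART-Seq v4 and libraries with Nextera XT. SMART-Seq does not mark strand, so reads of overlapping and antisense genes could not be told apart. Input RNA was not analysed here, so all differences are between the antibodies.

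The submitters' processing notes list FastQC 0.11.5, Trim Galore 0.5.0, STAR 2.6.0c, HTSeq 0.6.1p2, DESeq2 1.26.0, DESeq and the genome build mm10, with no settings. The data were 1 deposited table of genes. The authors gave FPKM per gene and library, per the file headers. The authors' baseMean is a signal, the mean of normalised reads over the libraries, per the file headers. The deposited log2 fold changes and their standard errors, the deposited test statistic (a score), the deposited p-values with their adjusted values, and the deposited linear fold change are the authors' DESeq2 comparison of 4E-T with IgG. No adjusted p was missing and the lowest baseMean was 2.63, so genes with fewer reads had been left out of the table.

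FPKM are not counts, so the main test used a log scale. Read numbers were nevertheless recovered: each gene's 4 FPKM and its baseMean gave whole reads for 100% of 86952 values, within a tolerance of 0.01 read. The recovery found all values of 3562 simulated genes. The FPKM turned out to be scaled by the same size factors as baseMean, not by the library totals. The recovered reads over the listed genes were 85828188 and 77919577 in IgG libraries 1 and 2, and 85451469 and 72769612 in 4E-T libraries 1 and 2. At this depth, sampling noise was small against the spread between libraries. For libraries of the same antibody, a chi-square test of the reads gave 31.2 (IgG) and 44.4 (4E-T) per degree of freedom, so none was a duplicate of another. The recovered reads also gave the exon length of each gene in bp, scaled on 10 mitochondrial genes.

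Genes with FPKM of at least 1 in at least 2 of the 4 libraries were tested, 12585 in all, and 9153 listed genes were not. limma 3.58.1 (R 4.3.3) was fitted to log2(FPKM + 1) with the antibody as the only term and with the trend and robust options. Differences are 4E-T minus IgG on this scale, which understates the change of low genes. p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Folds were taken from the log2 differences. The labels do not say whether the libraries came from separate cultures or animals, so p-values measure the spread between these 4 libraries, which may be technical. With 2 residual degrees of freedom per gene, the test relies on a spread shared across genes (27 prior degrees of freedom).

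Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists with at least 5 tested members, 24 of them, were tested against all other genes with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera relies on the 2 residual degrees of freedom, so it had little power to call any list. fry tests whether the genes of a list moved, on balance, one way, and does not compare them with other genes. Some genes stand in more than 1 list. The rule named Eif4enif1, the 12 genes with the largest difference in each direction, and up to 2 members per direction from each list. The 12 had to pass the threshold, have a mean FPKM of at least 5 in the higher group and have the same sign in both experiments. Predicted models, pseudogenes and mitochondrially encoded genes were left out of them. Where no member of a list passed, its 2 most abundant members were named. Some genes that the rule names are not reported here. Other genes named in the text as list members were chosen after their values were seen.

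Libraries were simulated with the means and depths of the 12585 genes and the spread that limma had estimated for them. limma called 47% of genes changed by 1.5-fold and 95% of genes changed by 2-fold, with 0.195% of unchanged genes called. The simulated spread was already shared across genes by limma, so these rates do not test whether that sharing holds in the data. camera called a shifted list and 0 of 100 unshifted lists. The simulated genes varied independently, and besides that list 200 genes were changed. False calls for lists of correlated genes were therefore not tested. Estimated correlations in the data ranged from -0.018 (P-body and mRNA repression factors) to 0.85 (mitochondrially encoded genes). The alternatives were other pseudocounts (0.1, 0.5), other filters, median ratio scaling, quantile normalisation, the experiment number as a block, limma without trend and robust, other thresholds and leaving out each library. After the table was seen, limma voom on the recovered reads, a lowess correction for gene length and a background subtraction were added. GC content was not analysed here because no genome sequence was used. Count models were not run on the recovered reads, since the deposited values are FPKM.

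Gene identifiers without their version matched the reference names for 21702 genes, and 18488 symbols were found in RefSeq. Coordinates are RefSeq gene spans on GRCm38.p6, the assembly that mm10 denotes. The spans of 41 of 102 named genes with coordinates overlap another RefSeq gene. Values of ribosomal protein, histone and zinc finger genes, of Kifc1 and Hsp90aa1, and of other genes with near-identical copies or processed pseudogenes are uncertain, since the notes do not say how shared reads were counted. Mitochondrial reads can be shared with nuclear copies of mitochondrial DNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.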

Results

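RNA bound in 4E-T immunoprecipitates of V-SVZ neurospheres was compared with RNA in control IgG immunoprecipitates, with 2 libraries per antibody. 4E-T, the product of Eif4enif1, binds the cap-binding protein eIF4E and takes part in translational repression in P-bodies, cytoplasmic granules of untranslated mRNA. The comparison asks which transcripts of neural precursors had a larger share in the 4E-T libraries than in the control. The values are scaled per library, so they do not show how much RNA each antibody recovered. A transcript called lower with 4E-T need not have been recovered less with it. The libraries held between 72769612 and 85828188 recovered reads over the listed genes. The first principal component of the log2 values held 86.0% of the variance. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.997 between the IgG libraries and 0.996 between the 4E-T libraries.

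At the preset correlation, the lists of chromatin regulators, Zfp genes, Notch, Wnt, BMP and hedgehog pathway genes and glycolytic enzymes were higher with 4E-T, while those of mitochondrially encoded, nuclear and long non-coding and ribosomal protein genes were lower. None of these calls held with an estimated correlation, where the lowest camera adjusted p was 0.707. That test had 2 residual degrees of freedom and little power, so the lost calls do not decide whether these lists moved. The estimated correlations were 0.85 for mitochondrially encoded, 0.79 for ribosomal protein, 0.40 for non-coding and 0.37 for Zfp genes. They were 0.19 for glycolytic enzymes, 0.070 for chromatin regulators and 0.045 for Notch and related pathways. Where genes vary together this strongly, p-values at the preset 0.01 can be far too small. Hes5, the Notch effector of neural stem cells, was 7.10-fold higher with 4E-T (log2 difference 2.83 ± 0.18, SE, n = 2 per antibody). Cacfd1 had the largest decrease of the named genes, and was 10.8-fold higher with IgG (log2 difference -3.44 ± 0.16). Of 12585 tested genes, 4318 were higher and 1912 lower with 4E-T at a limma adjusted p under 0.05, which is 49.5% of the tested genes. At least 2-fold changes were found in 449 of the higher and 240 of the lower genes. The split of calls depended on the scaling and on the genes included. With no filter on low values, the deposited scaling gave a median log2 difference of -0.0072 and 57.7% of calls higher. With the filter, the median tested gene had a log2 difference of 0.16. Median ratio scaling brought it to -0.0013. It centres each library on the tested genes, so a value near 0 was fixed in advance. With that scaling 49.6% of calls were higher (2922 higher, 2966 lower), and with quantile normalisation 52.8% (3157 higher, 2827 lower), against 69.3% as deposited. Without IgG library 2 there were 2389 higher and 1272 lower calls, and without IgG library 1 there were 1101 lower calls.

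**Figure D1:**
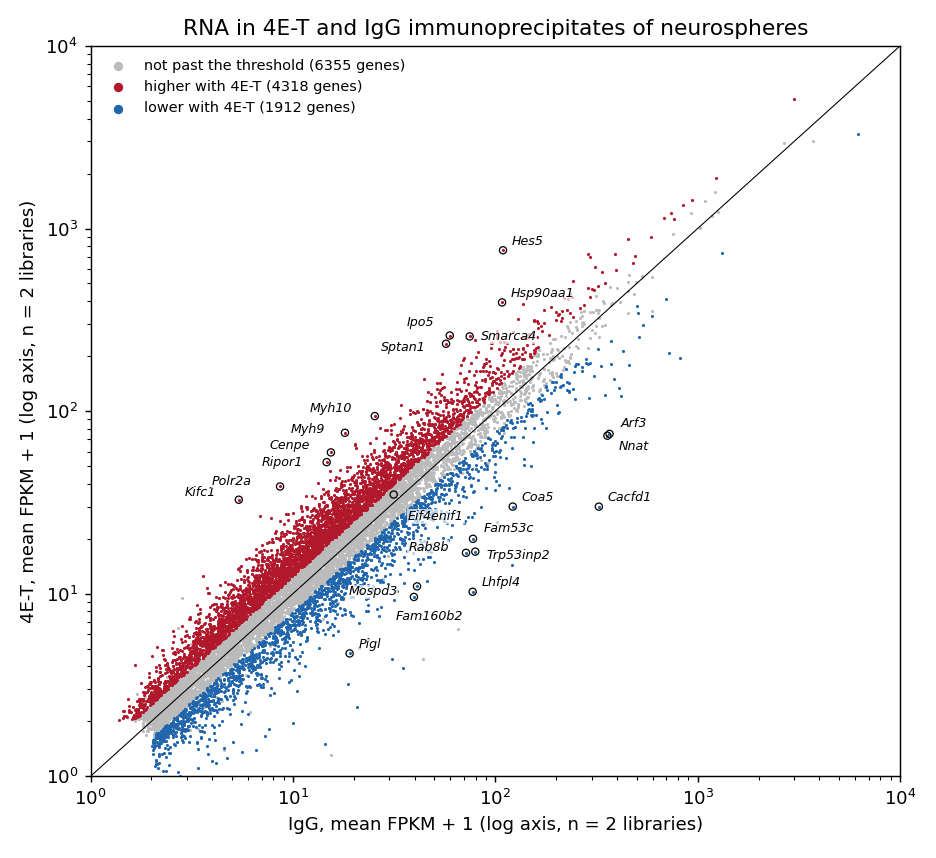
Mean FPKM + 1 of each tested gene with IgG (horizontal, log axis) and with 4E-T (vertical, log axis), each a mean of 2 libraries; the line marks equal values, colours mark the limma call and circles mark Eif4enif1 and the named genes with the largest differences. Hes5 lies farthest above the line and Cacfd1 farthest below it among the circled genes, and Eif4enif1 (log2 difference 0.15) lies near it.

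The transcript of the immunoprecipitated protein itself was at a similar level with both antibodies. Eif4enif1 (ENSMUSG00000020454.17; chromosome 11, 3202343 to 3244588, GRCm38.p6) had FPKM of 31.3 and 29.7 with IgG and 32.5 and 35.3 with 4E-T, a log2 difference of 0.15 ± 0.14 (SE; limma adjusted p = 0.390). Its sign turned with median ratio scaling (-0.010) and with quantile normalisation (-0.022). Among 53 tested P-body and mRNA repression factors, 22 were higher and 8 lower (23 and 8 adjusted over the list alone). The list was not called against other genes (camera adjusted p = 0.604), with a median log2 difference of 0.21. With no filter, where the other genes included low genes that were mostly higher with IgG, it was called higher (camera adjusted p = 0.0254). Edc4, a scaffold of the decapping complex, was higher by 1.46 ± 0.15 on the log2 scale and Zfp36l2, an AU-rich element binding protein, by 1.27 ± 0.14. The RNA-binding protein genes Msi2 (-1.22 ± 0.20) and Stau2 (-0.88 ± 0.14) were lower.

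Of the 12 genes with the largest increase, Hes5 (ENSMUSG00000048001.7; chromosome 4, 154960626 to 154962372) rose from an FPKM of 108 ± 31.0 (SD, n = 2) with IgG to 759 ± 26.3 with 4E-T (limma adjusted p = 1.36e-11). Polr2a, the largest subunit of RNA polymerase II (ENSMUSG00000005198.15; chromosome 11, 69733997 to 69758633), rose from 7.64 ± 1.10 to 37.7 ± 2.68 (limma adjusted p = 3.31e-12). Smarca4, the ATPase of the BAF chromatin remodelling complex (chromosome 9, 21616106 to 21704230), was 3.42-fold higher (log2 difference 1.77 ± 0.16). The nuclear import receptor gene Ipo5 was higher by 2.13 ± 0.16 on the log2 scale. Genes for non-muscle myosin heavy chains and spectrin were also among them, with Myh9 at 2.06 ± 0.15, Sptan1 at 2.01 ± 0.17 and Myh10 at 1.87 ± 0.15. Cenpe, a kinetochore motor, had a difference of 1.94 ± 0.14, and Kifc1, a spindle kinesin with the near-identical copy Kifc5b, 2.61 ± 0.15. The chaperone gene Hsp90aa1 (1.86 ± 0.18) and Ripor1 (1.83 ± 0.15) were also among the 12. Genes called higher were longer than other genes, with a median exon length of 3791 bp against 2750 bp for genes called lower and 2894 bp for genes not called.

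Of the 12 genes with the largest decrease, Cacfd1 (ENSMUSG00000015488.14; chromosome 2, 27009855 to 27021090) fell from an FPKM of 324 ± 49.9 (SD, n = 2) with IgG to 29.0 ± 3.64 with 4E-T (limma adjusted p = 2.37e-15). Lhfpl4, which encodes a partner of inhibitory synapse receptors (ENSMUSG00000042873.11; chromosome 6, 113168087 to 113195384), fell from 76.3 ± 3.38 to 9.24 ± 0.0743 (limma adjusted p = 2.37e-15). Arf3 (-2.29 ± 0.16), a Golgi GTPase, and Rab8b (-2.09 ± 0.15), a GTPase of vesicle transport, were lower on the log2 scale. Nnat, an imprinted gene within an intron of Blcap, had a difference of -2.27 ± 0.17, and Trp53inp2 of -2.23 ± 0.14. Fam160b2 (-2.04 ± 0.14), Pigl (-2.02 ± 0.13), Coa5 (-2.01 ± 0.17), Fam53c (-1.96 ± 0.14) and Mospd3 (-1.89 ± 0.15) were also among the 12. Genes that neural cells do not use also had more reads with IgG. Over 179 olfactory, vomeronasal and taste receptor genes there were 2721 and 3576 recovered reads with IgG against 598 and 765 with 4E-T.

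Chromatin regulator transcripts were higher with 4E-T almost throughout the list. Of 65 tested members, 58 were higher and 0 lower (60 and 0 adjusted over the list alone), with a median log2 difference of 0.70 and a camera adjusted p of 2.68e-12. With an estimated correlation the adjusted p was 0.707. Besides Smarca4, Crebbp, a histone acetyltransferase gene, was higher by 1.68 ± 0.14 (SE). These genes are long, with a median of 7786 bp. Zinc finger genes named Zfp were higher in 169 and lower in 20 of 328 cases (174 and 21 adjusted over the list alone; median 0.36; camera adjusted p = 0.000187, and adjusted p = 0.822 with an estimated correlation). Zfp292 (1.46 ± 0.14) and Zfp786 (1.43 ± 0.14) led them, and Zfp839 (-1.01 ± 0.14) and Zfp689 (-0.77 ± 0.14) were lower. Of 69 other zinc finger transcription factor genes, 36 were higher and 4 lower (36 and 6 adjusted over the list alone; median 0.38; camera adjusted p = 0.0268, and adjusted p = 0.822 with an estimated correlation). Klf7 (1.13 ± 0.14) and Zkscan6 (1.02 ± 0.14) were the highest, Zbtb12 (-0.70 ± 0.16) and Zic5 (-0.42 ± 0.13) the lowest. That call was lost without 4E-T library 2 (adjusted p = 0.0772) and after a correction for gene length (adjusted p = 0.314), and the adjusted p over all alternatives ranged from 2.35e-05 to 0.372. Zbtb12 was not called without IgG library 2 (limma adjusted p = 0.0786), and Zic5 not without IgG library 1 (0.0954), IgG library 2 (0.0694) or 4E-T library 1 (0.118). Homeobox, Sox, forkhead and other developmental transcription factors were higher in 36 and lower in 10 of 101 cases (35 and 10 adjusted over the list alone), and were not called as a list (camera adjusted p = 0.282). With no filter, where the other genes included low genes that were mostly higher with IgG, the list was called higher (camera adjusted p = 0.0122). Next to Hes5, Pou2f1 (1.17 ± 0.14) was higher, and Nfia (-1.16 ± 0.14) and Pou3f2 (-0.79 ± 0.14) were lower.

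Genes of the Notch, Wnt, BMP and hedgehog pathways were higher in 26 and lower in 2 of 42 cases, with the same counts adjusted over the list alone. The median log2 difference was 0.52, with a camera adjusted p of 0.00237 and an adjusted p of 0.707 with an estimated correlation. The Notch ligand gene Dll3 was higher by 1.42 ± 0.15 (SE), and the receptor genes Notch1 and Notch2 by 1.42 and 1.22. The BMP ligand gene Bmp7 was lower (-1.15 ± 0.14), as was the BMP receptor gene Bmpr1a (-0.33 ± 0.14), whose call was lost whichever library was left out (limma adjusted p 0.326 and 0.0643 without IgG libraries 1 and 2, 0.123 and 0.106 without 4E-T libraries 1 and 2). Of 31 receptor tyrosine kinase and ligand genes, 18 were higher and 1 lower, also over the list alone, and the list was not called (camera adjusted p = 0.139). With no filter, where the other genes included low genes that were mostly higher with IgG, it was called higher (camera adjusted p = 0.00777). Insr (1.01 ± 0.14) and Pdgfra (0.92 ± 0.17) were higher, and Epha5 (-1.01 ± 0.14) was lower.

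Markers of neural stem cells and radial glia were higher in 16 and lower in 3 of 31 cases, also over the list alone. Their median log2 difference was 0.46, and the list missed the threshold (camera adjusted p = 0.0583, and adjusted p = 0.822 with an estimated correlation). It was called without 4E-T library 1 (adjusted p = 0.0340), without 4E-T library 2 (adjusted p = 0.00172) and with median ratio scaling (adjusted p = 0.0356), and over all alternatives the adjusted p ranged from 2e-04 to 0.130. Besides Hes5, the extracellular matrix gene Tnc was higher (1.43 ± 0.29, SE), while Cd9 (-0.73 ± 0.16) and Emx2 (-0.71 ± 0.14) were lower. Neurogenic transcription factors and early neuroblast genes were higher in 7 and lower in 3 of 21 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.485). Prox1 (1.14 ± 0.13) was higher, and Cd24a (-0.84 ± 0.16) was lower. Neuron markers were higher in 1 and lower in 3 of 16 cases, also over the list alone, with a median of -0.14 and a camera adjusted p of 0.0443, or an adjusted p of 0.820 with an estimated correlation. Celf4 (-0.88 ± 0.13) and Syp (-0.73 ± 0.13) were lower and Grin1 (0.57 ± 0.13) was higher. The neuron call was lost without IgG library 2 (adjusted p = 0.111), 4E-T library 1 (adjusted p = 0.116) or 4E-T library 2 (adjusted p = 0.0809), with a range from 0.0116 to 0.276 over all alternatives. Oligodendrocyte lineage markers were higher in 5 and lower in 2 of 14 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.696). The precursor marker Cspg4 (1.70 ± 0.19) and Cnp (0.93 ± 0.15) were higher, and Lhfpl3 (-1.51 ± 0.14) was lower. Astrocyte markers were higher in 6 and lower in 3 of 20 cases, also over the list alone (camera adjusted p = 0.861). Aldh1l1 (1.25 ± 0.18) and Mfge8 (limma adjusted p = 2.47e-05) were higher, and Atp1b2 (-0.70 ± 0.15) and the water channel gene Aqp4 (-0.53 ± 0.13) lower, the last not without IgG library 1 (limma adjusted p = 0.0533).

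Markers of ependymal, immune, vascular and connective tissue cells were mostly under the FPKM minimum and were not tested as lists. Of 20 ependymal and cilia markers 4 were tested, and the most abundant of them, Foxj1 (0.024 ± 0.15) and Rsph1 (-0.22 ± 0.13), were not called. With median ratio scaling and quantile normalisation Rsph1 was called lower (-0.38 and -0.34, limma adjusted p = 0.0251 and 0.0385). Of 22 microglia and blood cell markers 1 was tested. Of 20 endothelial, mural and fibroblast markers 3 were tested, among them Pdgfra and Tagln (0.36 ± 0.13, limma adjusted p = 0.0255). The Tagln call was not kept with median ratio scaling (limma adjusted p = 0.204). It was also lost without IgG library 1 (0.0523), IgG library 2 (0.219) or 4E-T library 2 (0.10).

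Glycolytic enzyme transcripts were higher in 13 and lower in 0 of 18 cases (14 and 0 adjusted over the list alone), with a median log2 difference of 0.61. Aldoa is listed under 2 identifiers. The camera adjusted p was 0.00206, and the adjusted p 0.820 with an estimated correlation. Hk1, the first enzyme of the pathway, was higher by 1.27 ± 0.15 (SE) and Pfkp by 1.21 ± 0.14. Cholesterol and lipid synthesis genes were higher in 14 and lower in 5 of 28 cases (16 and 6 adjusted over the list alone; camera adjusted p = 0.282). The fatty acid synthesis genes Fasn (1.73 ± 0.16) and Acly (1.06 ± 0.16) were higher, and the sterol pathway genes Idi1 (-0.76 ± 0.15) and Insig1 (-0.74 ± 0.15) lower. Immediate early and stress response genes were higher in 16 and lower in 3 of 28 cases, also over the list alone (camera adjusted p = 0.187, but 0.0293 without 4E-T library 2, and from 0.000978 to 0.543 over all alternatives). Besides Hsp90aa1, Ier2 (1.24 ± 0.15) was higher and the chaperone partner gene Dnajb1 (-0.90 ± 0.14) lower. Atf4, a stress response transcription factor gene, had a difference of -0.48 ± 0.18, and its call was lost without IgG library 1 (limma adjusted p = 0.310), IgG library 2 (0.140) or 4E-T library 2 (0.385). The Atf4 difference was -0.76 without 4E-T library 1 and -0.19 without 4E-T library 2.

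Cell cycle genes were higher in 21 and lower in 4 of 42 cases, also over the list alone, with a median of 0.38 (camera adjusted p = 0.0443, and adjusted p = 0.822 with an estimated correlation). The list was not called after the length correction (camera adjusted p = 0.0694), with quantile normalisation (0.0507) or after background subtraction (0.0521). Besides Cenpe, the topoisomerase gene Top2a (1.61 ± 0.16, SE) was higher, while Hmgb2 (-0.86 ± 0.16) and Ccnd2 (limma adjusted p = 2.24e-05) were lower. The list call was lost without IgG library 1 (adjusted p = 0.101) or IgG library 2 (adjusted p = 0.0528), and the adjusted p ranged from 3.08e-05 to 0.101 over all alternatives. Proteasome subunit genes were higher in 17 and lower in 2 of 35 cases, also over the list alone, with a median of 0.34 (camera adjusted p = 0.0443, and adjusted p = 0.822 with an estimated correlation). That call was lost without IgG library 1 (adjusted p = 0.142), IgG library 2 (adjusted p = 0.0985) or 4E-T library 1 (adjusted p = 0.143), with a range from 0.000208 to 0.265 over all alternatives. Psmd1 (1.11 ± 0.16) and Psmc2 (0.95 ± 0.15) were higher. Psmd11 (-0.82 ± 0.15) and Psmc6 (-0.48 ± 0.15) were lower, the last not without IgG library 1 (limma adjusted p = 0.210).

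Mitochondrially encoded transcripts had the largest decrease of the lists. Of 10 tested, 0 were higher and 8 lower, also over the list alone, with a median log2 difference of -1.76 (camera adjusted p = 4.23e-10, and adjusted p = 0.707 with an estimated correlation). The cytochrome oxidase gene mt-Co1 fell from an FPKM of 820 ± 40.0 (SD, n = 2) with IgG to 194 ± 46.1 with 4E-T, and mt-Co3 had a difference of -2.07 ± 0.14 (SE). mt-Nd6 (-0.61) and mt-Atp6 (-0.65) were not called. Genes with mt- names took 0.347% and 0.371% of the recovered reads with IgG and 0.064% and 0.105% with 4E-T. Respiratory chain genes of the nuclear genome were higher in 17 and lower in 3 of 81 cases (14 and 3 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.861). Sdha (1.03 ± 0.17) and Ndufs1 (1.01 ± 0.17) were higher and Cox6b2 (-0.82 ± 0.14) lower. Sdhc (-0.57 ± 0.15) was lower too, but not without IgG library 2 (limma adjusted p = 0.136). Mitochondrial ribosomal protein genes were higher in 19 and lower in 7 of 78 cases (17 and 7 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.861). Mrps30 (0.79 ± 0.14) and Mrpl9 (0.69 ± 0.15) were higher and Mrpl32 (-0.54 ± 0.14) lower. Mrpl42 (-0.57 ± 0.14) was lower but lost its call without IgG library 2 (limma adjusted p = 0.0587). The medians of the nuclear respiratory chain and mitochondrial ribosomal protein lists were 0.0043 and -0.0057 with median ratio scaling.

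Nuclear and long non-coding RNAs were higher in 0 and lower in 9 of 12 cases (0 and 10 adjusted over the list alone), with a median of -0.59. The camera adjusted p was 2.19e-06, and the adjusted p 0.707 with an estimated correlation. Xist, the RNA that coats the inactive X chromosome and overlaps its antisense gene Tsix, had a difference of -1.14 ± 0.14 (SE), and Sox2ot, which contains the gene Sox2, of -1.04 ± 0.14. The nuclear RNAs Neat1 (-0.75) and Malat1 (-0.71) were lower too.

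Cytosolic ribosomal protein genes were higher in 2 and lower in 33 of 87 cases, also over the list alone, with a median of -0.29 and a camera adjusted p of 9.73e-10. The adjusted p was 0.822 with the estimated correlation of 0.79. The median was -0.051 in Exp1 and -0.54 in Exp2. These genes are short, with a median of 977 bp, and after the length correction their median was -0.14 (camera adjusted p = 2.00e-05). Rps12 (-1.08 ± 0.14, SE) and Rps15a (-1.02 ± 0.15) were the lowest. Rps4l, a transcribed pseudogene in RefSeq, was higher (0.47 ± 0.13). Its call was lost without IgG library 2 (difference 0.465) or 4E-T library 1 (difference 0.37). Translation initiation and elongation factor genes were higher in 18 and lower in 9 of 57 cases, also over the list alone (camera adjusted p = 0.696). Their median of 0.11 became -0.049 with median ratio scaling. Eif3c (1.11 ± 0.17) and the scaffold gene Eif4g1 (1.02 ± 0.15) were higher, and Eif1ad (-0.83 ± 0.15) and the cap-binding gene Eif4e2 (-0.69 ± 0.15) lower. Replication-dependent histone genes were higher in 4 and lower in 8 of 28 cases, also over the list alone, with a median of -0.13 (camera adjusted p = 0.0164, and adjusted p = 0.707 with an estimated correlation). Hist2h2ac (1.08 ± 0.13) and Hist1h2ad (0.65 ± 0.13) were higher and Hist1h4k (-1.02 ± 0.14) and Hist2h2be (-0.90 ± 0.13) lower. The histone call was lost without IgG library 2 (adjusted p = 0.0854), without 4E-T library 1 (adjusted p = 0.0641) and after a length correction (adjusted p = 0.584, median 0.12). Over all alternatives its adjusted p ranged from 0.00555 to 0.584.

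**Figure D2:**
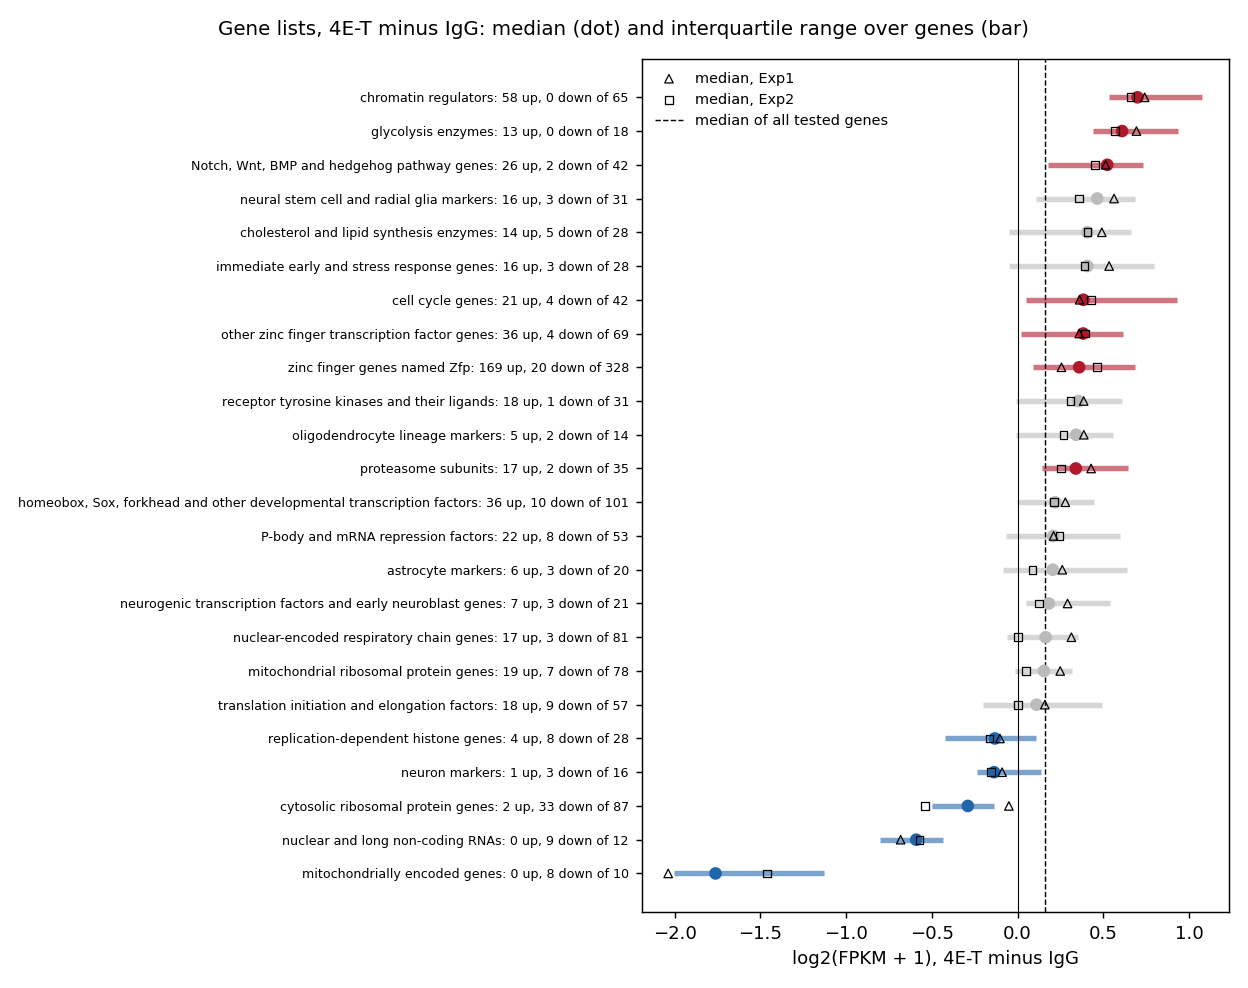
Median (dot) and interquartile range over genes (bar) of the log2 difference, 4E-T minus IgG, for the 24 lists tested, with the medians of Exp1 (triangles) and Exp2 (squares); red and blue mark lists called higher and lower by camera at the preset correlation. Mitochondrially encoded genes have the lowest median (-1.76) and chromatin regulators the highest (0.70), and the dashed line marks the median tested gene (0.16).

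Of the 24 lists, 7 were called higher and 5 lower at the preset correlation. With an estimated correlation 0 were called in either direction, the lowest adjusted p was 0.707 and no list had an unadjusted p under 0.05. With 2 residual degrees of freedom, that test could hardly have called a list. fry called 3 lists higher (P-body factors, Notch and related pathways, chromatin regulators) and 0 lower. These calls include the shift of the median tested gene, since fry was run on the deposited scaling. With median ratio scaling the medians of the 3 lists were 0.049, 0.36 and 0.54, in that order. camera did not call the P-body list (adjusted p = 0.604). At an unadjusted p under 0.05 fry had 10 higher and 3 lower.

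Transcripts of long genes were higher with 4E-T than transcripts of short genes. The shortest 10% of tested genes (median 541 bp) had a median log2 difference of -0.14 and the longest 10% (median 8044 bp) of 0.36. In the shortest group 7.31% of genes were higher and 27.8% lower, and in the longest 52.7% were higher and 9.13% lower. Across the 12585 genes, which are not independent replicates, Spearman's rho of length and difference was 0.244, with 0.184 in Exp1 and 0.280 in Exp2. For IgG library 2 minus IgG library 1 rho was -0.249, and for the 4E-T libraries it was 0.013. The longest minus the shortest 10% of genes differed by 0.51 between the antibodies (0.48 in Exp1, 0.58 in Exp2) and by -0.16 between the IgG libraries.

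**Figure D3:**
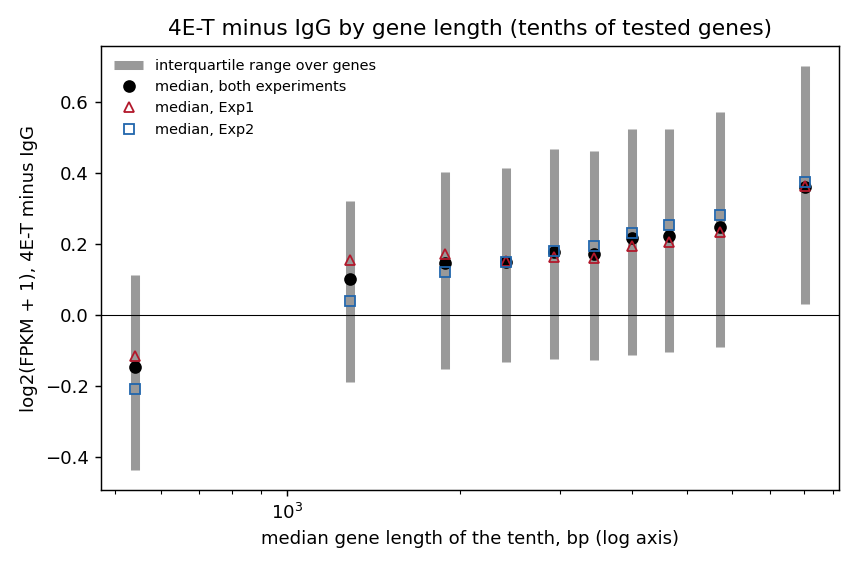
Log2 difference, 4E-T minus IgG, for 10 equal groups of the tested genes by exon length (log axis, bp); bars give the interquartile range over genes, dots the median and open symbols the medians of Exp1 and Exp2. The median goes from -0.14 in the shortest group to 0.36 in the longest.

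The authors' deposited table had 4358 genes higher and 2594 lower with 4E-T at an adjusted p under 0.05. Of these, 4196 higher and 1699 lower genes were among the 12585 tested here. The authors' deposited table and the limma fit shared 4111 higher and 1659 lower genes, with 0 genes called in opposite directions. Genes under the FPKM minimum made up 162 of the higher and 895 of the lower genes in the authors' deposited table. For Hes5 the log2 fold change in the authors' deposited table was 2.81, and for Eif4enif1 it was 0.15 (adjusted p = 0.430).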

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

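The voom, length-corrected and background-subtracted fits, and the restriction of the authors' comparison to the genes tested here, were chosen after seeing the data. Of the 4318 higher and 1912 lower calls, 4277 and 1815 were kept by voom on the recovered reads, 3925 and 1630 after the length correction, 4300 and 1881 with the replicate block, and 2922 and 1909 with median ratio scaling, with 0 calls of opposite sign in any alternative. The experiment number as a replicate block gave 4745 higher and 2099 lower genes, with 6 lists higher and 4 lower (the proteasome and neuron lists lost their calls, and no other list or named gene did). The correlation of same-numbered deviations across genes was 0.064 with only 2 pairs, and the labels do not say what the number marks, so the pairing was not used. Counts that moved by over 1.5 times were the following. Genes lower were 2966 with median ratio scaling and 3736 by voom with no filter, which tests more low genes. A fold of at least 2 left 449 genes higher and 240 lower. In the authors' deposited comparison it left 749 higher and 1250 lower, and the authors had 1699 lower genes among those tested here. With no filter 15 lists were higher and 3 lower, and by voom with no filter 13 and 3. In the former 8 lists gained a call. They were P-body factors, neural stem cell markers, receptor tyrosine kinases, lipid synthesis, stress response, nuclear respiratory chain, mitochondrial ribosomal proteins and developmental transcription factors. The comparison had changed: of the genes under the filter 71.9% had a higher mean FPKM with IgG. With them included the median difference fell from 0.16 to -0.0072. The gained calls therefore do not show that the lists themselves moved. At FPKM of at least 5 and with quantile normalisation 3 lists were lower, and the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and by fry 3 and 0. Leaving out 1 library at a time gave 2389 to 4259 higher genes, 1101 to 1755 lower genes, 5 to 8 lists higher and 3 to 5 lower; the lone library of an antibody was then assumed to vary like the others. Of 105 called named genes, 12 lost the call without some library (8 without IgG library 1, 10 without IgG library 2, 5 without 4E-T library 1 and 3 without 4E-T library 2), and none of the 105 changed sign in any alternative. Among those of the 12 named in the text, the limma adjusted p ranged over all alternatives from 4.09e-05 (Zbtb12) to 0.385 (Atf4). Results that changed sign had not been called, except the neuron and histone lists. Eif4enif1 went to -0.010 and -0.022, and Foxj1 to -0.14 and -0.14, with median ratio scaling and quantile normalisation, and leaving out 1 library put Foxj1 between -0.23 (without IgG library 1) and 0.28. The mean difference of a list from other genes turned, for mitochondrial ribosomal protein genes, to -0.00067 (pseudocount 0.5), -0.044 (FPKM of at least 5), -0.049 (quantile), -0.0049 (background subtracted), -0.051 (without IgG library 1) and -0.042 (without 4E-T library 1), with up to 0.052 without another library. For nuclear respiratory chain genes it turned to -0.016 (FPKM of at least 5), -0.0075 (quantile), -0.073 (without IgG library 1) and -0.047 (without 4E-T library 1), with up to 0.12 without another library. For translation factors it turned to 0.066 (no filter), 0.40 (voom, no filter), 0.0033 (without IgG library 1) and 0.056 (without 4E-T library 2), with down to -0.074 without another library. It turned for P-body factors to -0.030 (length corrected, with and without the block) and for astrocyte markers to -0.016 (without 4E-T library 1), with up to 0.17 without another library. By voom with no filter neuron markers had 0.013 and histones 0.21. The cause was not tested. Chromatin regulators, glycolysis, Notch and related pathways, Zfp genes, ribosomal proteins, non-coding RNAs and mitochondrially encoded genes kept their calls in every alternative run with camera at the preset correlation. Count models on the recovered reads and a GC correction were planned and not run. At 2 libraries per antibody, the spread between libraries limits the calls more than depth does.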

Other observations

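The gene families below, the test of length between IgG libraries, the test of non-coding RNAs and the comparison of the FPKM of lower genes with receptor genes, and the repeat-like gene models, were chosen after the results were seen. Tested genes were grouped by the letters before the first digit of their symbol, and 68 families, each with at least 15 tested members, were tested with camera at the preset correlation. In these, 11 families were higher and 11 lower with 4E-T relative to the other tested genes. Of the lower ones, Tmem and Fam genes had median log2 differences just above 0 (0.012 and 0.047). With an estimated correlation, where camera had little power, the adjusted p of each family named here was 0.995. Kinesins (Kif genes, motors that move along microtubules) were higher in 23 and lower in 0 of 30 cases, with a median log2 difference of 0.66 (camera adjusted p = 0.000124). Nucleoporins (Nup) were higher in 17 and lower in 0 of 19 (median 0.67), and the enzymes that charge tRNAs, added as a family by name, in 18 and 0 of 20 (median 0.71; camera adjusted p = 0.000363 for both). RNA helicases followed, with 12 higher and 0 lower of 15 Dhx genes (median 0.67) and 22 higher and 1 lower of 34 Ddx genes (median 0.49). Integrator subunits (Ints) were higher in 11 and lower in 0 of 15 cases (median 0.56; camera adjusted p = 0.00627). Of 22 Arl genes, which encode small GTPases, 0 were higher and 7 lower (median -0.21; camera adjusted p = 0.00223), and of 58 Rab genes 7 were higher and 15 lower (median -0.076; camera adjusted p = 0.00703). Ube genes, named for ubiquitin-conjugating and related enzymes, were higher in 5 and lower in 15 of 40 cases (median -0.13; camera adjusted p = 0.00406). After the length correction 18 of the 22 called families kept an adjusted p under 0.05, the ones above among them, and 4 did not (Rpl, Mir, Usp and Hist).

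Long genes were higher with 4E-T. Background in the IgG libraries that masks only low genes is argued against as the whole reason. Spearman's rho across the 4106 genes with a mean FPKM of at least 20 was 0.239. An uneven background that also reaches such genes stays open. Length was not the whole reason for the higher chromatin regulators, whose difference from other genes was 0.48 after the length correction (camera adjusted p = 3.01e-08 at the preset correlation; before the length correction the list was not called with an estimated correlation, adjusted p = 0.707). A length bias between libraries stays open: the longest minus the shortest 10% of genes gave -0.16 for IgG library 2 minus IgG library 1, against 0.51 between the antibodies and 0.033 between the 4E-T libraries, while rho was -0.249 between the IgG libraries, 0.244 between the antibodies and 0.013 between the 4E-T libraries. A preference of 4E-T for long mRNAs, a biological explanation, and a loss of long RNA in the controls could both give the trend and were not told apart.

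Genes silent in neural cells were higher with IgG. Of the 179 olfactory, vomeronasal and taste receptor genes, 96.6% had a higher mean FPKM with IgG, and relative to all recovered reads their reads were 4.53-fold higher in Exp1 and 4.37-fold in Exp2, and of 9153 genes under the FPKM minimum 71.9% did. A candidate explanation is a background, such as genomic DNA or unspliced RNA, that reaches silent genes and is larger relative to RNA in the controls; its kind was not tested. For the summed FPKM of 6 repeat-like gene models, the median fold of IgG over 4E-T was 48.2 in Exp1 and 9.0 in Exp2. These models were chosen after the results were seen, so they cannot decide whether the background had 1 ratio over all sequences. An even background, of the same FPKM in every gene, is argued against as the whole reason for the lower tested genes, since 88.7% of them differed by more than the 0.886 FPKM of the most different receptor gene (median 4.44 FPKM). Subtracting each library's median receptor FPKM left 1871 genes lower but was too small a step to decide this, and an uneven background stays open.

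Mitochondrially encoded transcripts were lower with 4E-T. A lower level of all respiratory chain transcripts is argued against, since the nuclear-encoded genes had a median log2 difference of 0.16 against -1.76 for the mitochondrial ones. Nuclear and long non-coding RNAs were lower as well (camera adjusted p = 2.19e-06, but 0.707 with an estimated correlation). A lower share of RNA kept outside the cytosol in the 4E-T immunoprecipitates could give both decreases. The list cannot decide this, since it holds long non-coding RNAs whose place in the cell was not measured. The list was fixed beforehand, but its use as this test was chosen after the results were seen. The explanation is a hypothesis, and nonspecific binding of organelle or nuclear RNA in the controls would give the same values.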
